A study of Mus musculus with 8 samples.

How the data were processed

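The series holds 8 RNA sequencing libraries of mouse melanocyte stem cells, 4 control and 4 Bmi1-deleted, from the dorsal skin of mice on a mixed background at postnatal day 21. Per the labels, skin was digested with collagenase and trypsin, and cells negative for DAPI and for autofluorescence and positive for Dct-driven GFP were sorted. RNA from more than 10000 sorted cells per sample was used, 1 ng per library, with a stranded total RNA kit, 15 cycles of PCR, enzymatic removal of ribosomal fragments and 15 more cycles of PCR. The kit has no molecular identifiers that the sources used here mention, so counts include PCR copies. Floors cover counting error only, while SDs and standard errors also take in the spread between libraries. Libraries were grouped by genotype as labelled, and the number in each sample's title was taken as its replicate number.

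The authors deposited 2 tables with 1 column per library and 54418 Ensembl genes. One holds estimated counts per gene, which the authors made with Salmon 1.2.1 and build mm10 per the submitters' processing notes and deposited as whole numbers without normalisation; the column sums differ, from 8882656 to 10368174. The other holds log2 values that the authors deposited as the binary logarithm of TPM plus 1, since undoing the logarithm and subtracting 1 gives columns that sum to 1e+06. The annotation version, decoy sequences, bias correction, strand setting and rounding step behind both tables are not given in the sources used here. Gene names and positions came from GENCODE mouse release M21, in which 54096 of the identifiers had a symbol. Members of lists were counted by gene identifier, so a symbol with more than 1 identifier counts more than once. All columns of both tables were used. Raw reads were not analysed here.

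TPM divide each count by an effective length, and Gm23935 alone took 73.8% to 85.6% of the TPM of a library but, with CT010467.1, 2.62% to 5.46% of the counts. Counts were therefore the main table and TPM an alternative. Counts were filtered with filterByExpr of edgeR 4.0.16 by group, which kept 16011 genes, scaled by TMM, and compared with its quasi-likelihood F test (robust, two-sided, R 4.3.3). Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values without another name are from this test. A rise or fall is Bmi1-deleted against control, the standard error of a log2 change was taken from its F statistic, and levels are CPM scaled by TMM with the SD over 4 libraries. The median log2 change of all tested genes was 0.01. Pairs of replicates of 1 group differed by 12.5 to 38.8 times the variance of counting (chi-square per degree of freedom). As the counts include PCR copies, this does not show whether depth was the main limit. A count of 0 was given a floor of 3 counts per library, 0.289 to 0.338 CPM.

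The replicate numbers were checked as a possible pairing. After centring within genotype, libraries with the same number correlated across genes at 0.124 to 0.186. Genes are not independent replicates, so no p is given. Libraries of replicates 1 and 2 also resembled each other across numbers, as did those of 3 and 4 (mean correlation 0.166), and differed from the others (mean −0.162). Only 4 of the 8 libraries matched best with their own number. The first principal component (27.2% of variance) parted replicates 1 and 2 from 3 and 4, and the second (16.3%) parted the genotypes. No label gives a batch, litter or day, so the fit without a block stayed the main one and the replicate number as a block was an alternative, printed beside results where it changed a call.

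Single values were compared by exact two-sided permutation over the 70 assignments of 8 libraries, whose smallest p is 0.0286. The 43 gene lists, 38 of them with at least 5 tested members, were tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided), with camera and an estimated correlation, and with fry, each adjusted over the lists tested. Camera compares a list with all other genes, and fry asks whether its members move one way on balance. Lists covered pigment and melanosome genes, lineage regulators, the Ink4a/Arf axis and cell cycle inhibitors, Hox genes, Polycomb-repressed developmental regulators, subunits of both Polycomb complexes, glutathione S-transferases, antioxidant genes, stress, cell cycle, metabolism and signalling genes, Schwann cell and adhesion genes, and markers of 13 other cell types or states. Each list's members were also counted at a p adjusted over the list alone. Of the 17 tested fibroblast markers 0 were members of another list and 12 had at least 10 CPM in control libraries.

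The rule for named genes took Bmi1, Cdkn2a and Cdkn2b, the pigment and lineage genes Dct, Tyr, Tyrp1, Pmel, Mitf, Kit and Sox10, and Ezh2. It added the 12 genes with the largest increase and the 12 with the largest decrease among those that passed, did not overlap between groups and had a mean of at least 1 CPM, and left out predicted gene models, of which 0 passed. Places left over were filled by the smallest unadjusted p with the same conditions. In each list up to 4 members that passed, or else the most abundant, were named, and in lists of other cell types the 2 most abundant. The grouping, the main test, the lists, this rule and 24 alternative settings were chosen before the data were examined, and 11 further settings afterwards.

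The alternatives chosen first were RLE and upper quartile scaling, no filter and a filter at 10 CPM in 4 libraries, DESeq2 1.42.0, limma-voom without and with sample weights, limma trend on the deposited log2 TPM (at least 1 TPM in 4 libraries), the replicate block, inferred sex, 1 surrogate variable from sva 3.50.0 and the mitochondrial share as covariates, an adjusted p under 0.1, an absolute log2 change of at least 1, each library left out in turn, and for lists the estimated correlation and fry. Chosen after seeing the data were a 2-level block (replicates 1 and 2 against 3 and 4), the fibroblast score as a covariate without and with the replicate block, each pair of replicates alone, the block without 1 pair in turn, TPM rescaled by TMM without Gm23935, and the block with an estimated correlation. The pipeline was tested on simulated data of the same size with 50 changed genes per fold. These were drawn from genes with a fitted mean of at least 50 counts, so the rates do not cover genes of lower level. At 2-fold the main test found 42% and at 4-fold 88%, with 3 false calls among 15265 genes. With the block it found 64% and 90%, with 13 false calls among 15159 genes. The blocked fit had its own simulation with replicate differences, which the first simulation lacked, so the rates of the fits cannot be compared directly.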

Results

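RNA was sequenced from melanocyte stem cells, the cells of the hair follicle that renew its pigment cells, sorted from the dorsal skin of mice at postnatal day 21. The sorted cells were live, not autofluorescent and positive for a doxycycline-fed histone-GFP reporter driven through Dct, a gene of melanin synthesis. There were 4 libraries from mice with floxed Bmi1 and no Cre (control) and 4 from floxed mice that also carried Tyrosinase-Cre (Bmi1-deleted). Control libraries 1 to 4 held 9321888, 9466711, 9260536 and 8882656 counts, and Bmi1-deleted libraries 1 to 4 held 9172699, 10368174, 9088780 and 9076517. Xist and Y-linked counts marked control libraries 1 and 3 and Bmi1-deleted library 1 as female and the others as male. No label says that the replicates came from separate animals, so the p-values measure only the spread between these samples. None of 7 measures of library quality differed between the groups, the smallest exact two-sided permutation p being 0.2, for the share of the library's TPM (the transcript abundance unit of the second deposited table) held by the predicted gene Gm23935, 80.3% ± 5.05 in control and 83.5% ± 1.39 in Bmi1-deleted libraries (SD, n = 4).

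The comparison asked how loss of Bmi1, a subunit of Polycomb repressive complex 1 that keeps developmental genes and the Ink4a/Arf locus silent, changed the RNA of these cells. Bmi1 itself (ENSMUSG00000026739, mm10 chromosome 2, 18677018 to 18686629) had 796, 743, 705 and 859 counts in the control libraries and 627, 713, 626 and 607 in the Bmi1-deleted libraries. Its normalised level was 83.4 ± 10.0 CPM (counts scaled to 1e+06 per library; SD, n = 4) in control and 69.6 ± 0.880 in Bmi1-deleted libraries, 83.5% of control. The groups did not overlap (exact two-sided permutation p = 0.0286, the smallest that 70 assignments can give), but the gene did not pass the test across all genes (log2 change −0.26, SE 0.12, edgeR adjusted p = 0.607). Which exons were deleted is not given in the sources used here, and whole-gene counts include reads outside them. In the deposited TPM, which come from the same reads but divide by an effective transcript length, Bmi1 was 30.4 ± 6.14 in control and 13.4 ± 4.84 in Bmi1-deleted libraries (n = 4, exact two-sided permutation p = 0.0286). The ratio of TPM to CPM, relative to the median gene, changed by −0.75 on the log2 scale, and 29 of 8934 genes with a mean of at least 100 counts changed further down. The libraries differed: Bmi1-deleted 2 had 1.09, close to 1.135 in control 2, the lowest control. Bmi1-deleted 1, 3 and 4 had 0.629, 0.345 and 0.081. This ratio was computed after the Bmi1 values were seen.

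In the Bmi1-deleted cells 14 genes rose and 1 gene fell among 16011 tested. Those that rose were led by the cell cycle inhibitor gene Cdkn2a and by developmental transcription factor genes, Tbx15, Meis2, Prdm8, Foxf1, Hoxd8 and Tbx3. The gene that fell was Itga9, an integrin subunit. The groups did not overlap in CPM for any of these 15 genes, so all 4 same-numbered pairs of libraries necessarily went in the same direction. Across all genes, 1324 had an unadjusted p under 0.05, and 830 genes, 5.18% of those tested against 2.86% given by chance, had groups that did not overlap. With the replicate number as a block the counts were 273 higher and 113 lower, and all 15 genes were among them. Replicates 1 and 2 alone gave 83 higher and 73 lower genes, and replicates 3 and 4 alone 11 and 6. On the deposited log2 TPM 1 gene rose and 1 fell, with 0 of the 15 genes among them.

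Cdkn2a, which encodes the tumour suppressors p16 and p19 and is a classic target of Bmi1 repression, was silent in control cells and expressed after deletion. All 4 control libraries held 0 counts and the Bmi1-deleted libraries held 85, 50, 38 and 46, or 5.84 ± 2.32 CPM before scaling factors (SD, n = 4). Against a floor of 3 counts per library this was at least 17.3-fold higher (adjusted p = 0.00736). Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, rose from 20.5 ± 3.27 to 49.9 ± 8.93 CPM (log2 change 1.28, SE 0.19, adjusted p = 0.0136), although it passed in only 2 of 8 fits that each left out 1 library, those without control 1 and Bmi1-deleted 4, with a highest adjusted p of 0.0805. Cdkn2b, the neighbour of Cdkn2a, stood at 1.67 ± 1.38 and 1.61 ± 1.33 CPM (adjusted p = 0.994), a depth at which only a large difference would be detectable. Of the 10 tested inhibitor genes of the Ink4a/Arf list, 2 rose and 0 fell, and 3 rose and 1 fell adjusted over the list alone. The list as a whole was higher by camera (median log2 change 0.11, adjusted p = 0.031) but not with an estimated correlation (adjusted p = 0.34 with an estimated correlation) nor with the replicate block (adjusted p = 0.0691). Cdkn2a lies above the list's median both at its fitted value and at its bound. The list's mean log2 change was 0.99 against its median of 0.11, with Cdkn2a fitted at 8.79, so the camera call may rest largely on this gene. The camera call was also lost without control 1, 3 or 4 and without Bmi1-deleted 1 or 2, with adjusted p from 0.0512 to 0.0772. It was lost as well with a filter of 10 CPM in 4 libraries, which drops Cdkn2a (median 0.05, adjusted p = 0.417).

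Developmental transcription factor genes that Polycomb commonly represses were higher in the Bmi1-deleted cells. Tbx15 (ENSMUSG00000027868, chromosome 3, 99240381 to 99354259), a T-box factor of limb and skin patterning, rose from 1.01 ± 0.458 to 22.7 ± 5.21 CPM (log2 change 4.47, SE 0.37, n = 4, adjusted p = 0.00022). Meis2 (ENSMUSG00000027210, chromosome 2, 115863064 to 116065839), a homeobox partner of Hox proteins, rose from 2.95 ± 1.23 to 24.2 ± 2.60 CPM (3.02, SE 0.31, adjusted p = 0.00142). Foxf1 (chromosome 8, 121084386 to 121088144), a forkhead factor of mesenchyme, rose from 5.08 ± 1.69 to 24.8 ± 7.52 CPM (2.28, SE 0.31, adjusted p = 0.00736). Its divergent neighbour is the non-coding gene Fendrr, and use of strand in the counting is not given in the sources used here. Tbx3, a T-box factor known for repressing the Ink4a/Arf locus, rose from 19.5 ± 7.25 to 66.8 ± 12.5 CPM (1.78, SE 0.24, adjusted p = 0.00822), and did not pass without control 2 (adjusted p = 0.0619). Of the 128 genes on this list 45 were tested. The count filter keeps genes counted in 1 group alone, so the tested members can favour genes that changed. The values of the list do not cover the members left out. Of the 45 tested, 4 rose and 0 fell, and 12 rose and 2 fell adjusted over the list alone. The list's median log2 change was 0.48 (camera adjusted p = 2.1e-07; adjusted p = 0.0584 with an estimated correlation), and fry, which asks whether the members move one way on balance, gave an adjusted p of 0.00204.

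Hoxd8, a homeobox gene of the trunk, rose from 3.23 ± 0.990 to 15.5 ± 3.87 CPM (log2 change 2.26, SE 0.33, n = 4, adjusted p = 0.0142). It was the 1 member of 19 tested Hox genes to pass, over all genes and adjusted over the list alone, and it did not pass without control 2 or 4 or without Bmi1-deleted 1 or 2 (highest adjusted p = 0.0751). The median of the 19 tested Hox genes was 0.79 (camera adjusted p = 0.000955, adjusted p = 0.34 with an estimated correlation). The list names 39 Hox genes, and the members left out by the count filter are not covered. Markers of fibroblasts, which express many of these developmental genes, were higher in the same libraries by a median of 0.85. With the fibroblast score of each library as a covariate, added after seeing the data, Tbx15, Meis2, Foxf1 and Tbx3 still passed and Hoxd8 did not (log2 change 1.92, adjusted p = 0.0795).

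**Figure D1:**
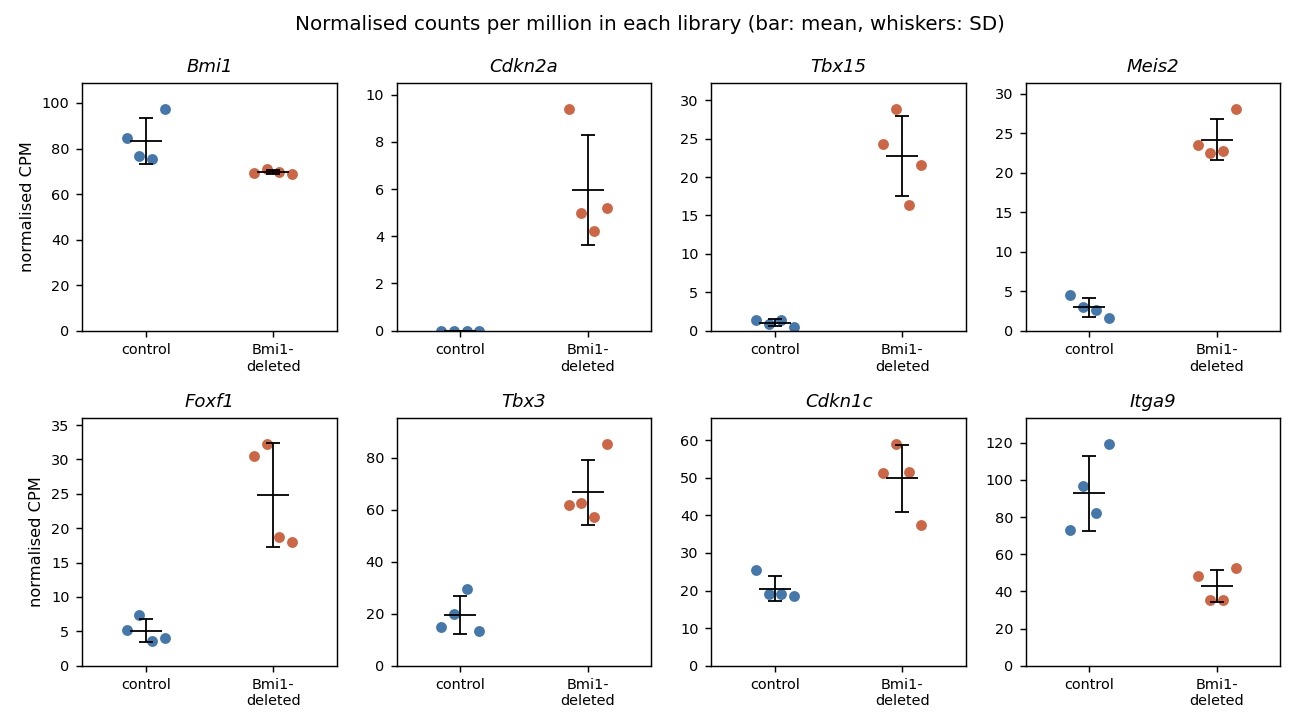
Normalised CPM (vertical axes, from 0) of 8 genes in each of 4 control and 4 Bmi1-deleted libraries, with the mean and SD; points are libraries 1 to 4 from left to right. Cdkn2a was at 0 in every control library, and in all 8 genes the groups do not overlap.

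The other genes that rose had varied roles. Prdm8, a repressor of the PR-domain family, rose from 2.74 ± 1.13 to 21.3 ± 3.62 CPM (log2 change 2.95, SE 0.33, n = 4, adjusted p = 0.00248), and Igf2bp3, an RNA-binding protein of embryonic tissue, from 9.80 ± 2.72 to 37.9 ± 4.83 CPM (1.95, SE 0.22, adjusted p = 0.00272). Mmp2, a secreted matrix protease, rose from 44.5 ± 6.23 to 103 ± 11.4 CPM (1.21, SE 0.14, adjusted p = 0.00319). Zdbf2, an imprinted gene, rose by 1.21 (adjusted p = 0.019) and Rflna, a regulator of the actin-binding filamins, by 1.37 (adjusted p = 0.0267). The rule for naming genes left out 2 of the 14, Peg3 and Epas1, which are named after their values were seen. Peg3, an imprinted zinc finger gene, rose from 149 ± 26.4 to 308 ± 11.7 CPM (adjusted p = 0.00552), and Epas1, a hypoxia-inducible factor, from 35.6 ± 4.09 to 69.3 ± 8.02 CPM (adjusted p = 0.019). Of the 15 genes, 8 passed with each library left out in turn, namely Cdkn2a, Tbx15, Meis2, Prdm8, Foxf1, Igf2bp3, Mmp2 and Peg3. Epas1 passed in 3 of those 8 fits (without control 1 or 4 or Bmi1-deleted 3; highest adjusted p of the others 0.0937), Zdbf2 in 2 (without control 1 or Bmi1-deleted 1; 0.0825) and Rflna in 1 (without Bmi1-deleted 4; 0.101). With inferred sex as a covariate Zdbf2, Rflna and Itga9 did not pass. The fibroblast score as a covariate ended the calls of Cdkn1c (0.97, adjusted p = 0.0817), Rflna (1.08, adjusted p = 0.121) and Itga9 (−0.92, adjusted p = 0.121), besides that of Hoxd8. With it Adcy7 (−1.84, adjusted p = 0.00869), Mcam (0.79, adjusted p = 0.0168) and Mt2, a metallothionein (−1.17, adjusted p = 0.0351), the last 2 named after their values were seen, passed.

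Itga9 (ENSMUSG00000039115, chromosome 9, 118606690 to 118901003), which pairs with integrin beta 1 in cell adhesion, fell from 92.8 ± 20.1 to 42.8 ± 8.79 CPM (log2 change −1.12, SE 0.18, n = 4, adjusted p = 0.0352). It passed without control 1 or without Bmi1-deleted 4 but with no other library left out (highest adjusted p = 0.153). The rule filled its remaining places with 11 genes that had separated groups but did not pass. Lgr6, a receptor of skin stem cells, stood at 46.7 ± 11.01 and 21.1 ± 3.22 CPM (adjusted p = 0.0515), and Adcy7, an adenylyl cyclase, at 43.6 ± 8.64 and 17.1 ± 4.97 (adjusted p = 0.0515). Bnc2, a zinc finger gene linked to pigmentation, had a log2 change of −0.88 (adjusted p = 0.0724), and Ednrb, the endothelin receptor of melanocyte development, of −0.68 (adjusted p = 0.0997). The others were Eogt (−1.23), Npnt (−1.17), Sgip1 (−0.99), Mdfic (−0.97), Fchsd2 (−0.69), Gsta1 and Gsta2. All 11 passed with the replicate block, with adjusted p from 0.00102 for Gsta2 to 0.015 for Mdfic. With the block and each pair left out in turn only Lgr6, Bnc2, Eogt and Gsta2 passed in all 4 fits. Adcy7 and Fchsd2 passed in 3 (highest adjusted p 0.0502 and 0.0908), Ednrb, Npnt and Gsta1 in 2 (0.1, 0.126 and 0.107), and Mdfic and Sgip1 in 1 (0.167 and 0.157).

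The list of glutathione S-transferase genes, which detoxify reactive compounds, was chosen from memory of what the study reported on these samples, so its direction is not independent evidence. Of 22 tested members 0 passed over all genes, and 0 rose and 3 fell adjusted over the list alone. With the replicate block 3 fell, Gsta2, Gsta1 and Gstp1, the last in 2 of 4 fits that each left out 1 pair (highest adjusted p 0.0596). Gsta1 stood at 33.5 ± 10.2 CPM in control and 12.5 ± 4.29 in Bmi1-deleted libraries (adjusted p = 0.0875, 0.00697 with the block), and Gsta2 at 25.4 ± 8.75 and 7.13 ± 3.28 (adjusted p = 0.0803, 0.00102 with the block). The pair are close paralogs, so reads are shared out between them with uncertainty. Gstm1 stood at 47.4 ± 3.56 and 45.6 ± 4.46 CPM (adjusted p = 0.967). The whole list had a median of −0.12 (camera adjusted p = 0.171) and passed without control 2 (adjusted p = 0.0393) and with a filter of 10 CPM in 4 libraries (median −0.27, adjusted p = 0.00601). Of 45 antioxidant genes, most under NRF2, 0 passed, over all genes or adjusted over the list alone, and with the block 2 rose and 1 fell (median −0.05, camera adjusted p = 0.215); the iron store gene Fth1 stood at 556 ± 49.9 and 530 ± 46.4 CPM.

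Pigment genes were lower in the Bmi1-deleted cells as a group. Of 25 tested genes of melanin synthesis and the melanosome, 0 passed over all genes, and 0 rose and 3 fell adjusted over the list alone; the median log2 change was −0.63 (camera adjusted p = 7.0e-10; adjusted p = 0.34 with an estimated correlation), and the list's mean level was lower in all 4 pairs. With the replicate block 10 of them fell. Dct stood at 4997 ± 1295 CPM in control and 3219 ± 1401 in Bmi1-deleted libraries (adjusted p = 0.639, 0.00261 with the block). The other enzyme genes Tyr (−0.98, adjusted p = 0.425, 0.00513 with the block) and Tyrp1 (−0.77, 0.395 and 0.000756) and the melanosome matrix gene Pmel (−0.81, 0.577 and 0.000305) went the same way. With the block and each pair left out in turn Dct, Tyrp1, Pmel and Mitf passed in all 4 fits, and Tyr and Kit in 3 (highest adjusted p 0.0744 and 0.0632). Of 27 lineage regulators 0 passed over all genes, and 0 rose and 2 fell adjusted over the list alone (median −0.05, camera adjusted p = 0.342). With the block 5 fell, among them the master regulator Mitf (−0.70, adjusted p = 0.00242) and the growth factor receptor Kit (−0.66, adjusted p = 0.00595), while Sox10, a neural crest factor upstream of Mitf, had 0.16 (adjusted p = 0.588 with the block, 0.818 without). Fibroblast markers, with a median of 0.85, moved with the same groups, and with their score as a covariate, added after seeing the data, Dct had 0.08 and Mitf 0.00. With the block as well they had −0.19 and −0.28 (adjusted p = 0.885 and 0.814).

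Genes of neural crest and Schwann cells, which share their origin with melanocytes, were higher as a list. Fibroblast markers were higher in the same libraries (median 0.85). Of 28 tested members 0 passed over all genes, and 7 rose and 1 fell adjusted over the list alone; with the block 12 rose and 1 fell. The median was 0.47 (camera adjusted p = 8.41e-08; adjusted p = 0.51 with an estimated correlation). Erbb3, a neuregulin receptor, stood at 649 ± 23.0 CPM in control and 763 ± 38.7 in Bmi1-deleted libraries (adjusted p = 0.59), and Pmp22, a membrane protein gene, at 583 ± 172 and 784 ± 150 (adjusted p = 0.633, 0.0294 with the block). Pmp22 passed in 1 of 4 blocked fits that each left out 1 pair (highest adjusted p 0.207) and had −0.003 with the fibroblast score as a covariate. Of 31 adhesion and migration genes 0 rose and 1 fell, Itga9, and 3 rose and 1 fell adjusted over the list alone (median 0.32, camera adjusted p = 0.00608; adjusted p = 0.51 with an estimated correlation). With the block 9 rose, among them Mcam, an adhesion molecule of melanocytic cells (0.68, adjusted p = 0.00124), and Tnc, a matrix protein (0.90, adjusted p = 0.00247), which are named after their values were seen. The adhesion call was lost without Bmi1-deleted 1 (adjusted p = 0.094) or Bmi1-deleted 2 (adjusted p = 0.072).

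Markers of fibroblasts were the other cell type's genes that moved most clearly with genotype. Of 17 tested markers 0 passed over all genes, and 8 rose and 0 fell adjusted over the list alone; with the block 11 rose. The median was 0.85 (camera adjusted p = 3.15e-09; adjusted p = 0.435 with an estimated correlation), and the score was higher in all 4 pairs. The collagen genes Col3a1, 2748 ± 668 and 5349 ± 1397 CPM (adjusted p = 0.136, 0.000192 with the block), and Col1a1, 1262 ± 319 and 3131 ± 1699 (adjusted p = 0.38, 0.00306 with the block), were the most abundant. Without each pair in turn Col3a1 passed in 4 and Col1a1 in 3 of 4 blocked fits. Endothelial (14 tested, median 0.78), mural (9, 0.68) and myeloid (13, 0.57) markers passed by camera, with adjusted p of 0.0194, 0.00951 and 0.0232, and all 3 were lost without Bmi1-deleted 1 (adjusted p = 0.375, 0.136 and 0.136) and with an estimated correlation (adjusted p = 0.51, 0.435 and 0.37 with an estimated correlation). The endothelial call was also lost without control 4 (adjusted p = 0.0561), and the myeloid call without control 1 (0.0689) and with the block (0.0789). Basal keratinocyte (16 tested, median 0.05, adjusted p = 0.988), hair follicle (15, 0.03, 0.908), suprabasal keratinocyte (16, 0.86, 0.11) and sebocyte markers (11, 0.44, 0.0734) did not pass, although the suprabasal list passed without Bmi1-deleted 3 or 4 (adjusted p = 0.00459 and 0.00103) and the sebocyte list without control 4 or Bmi1-deleted 1 or 3 (0.0404, 0.0321 and 0.00547). Both lists hung on single libraries, the suprabasal median being 0.10 without Bmi1-deleted 1 and the sebocyte median 0.05 without Bmi1-deleted 2. The abundant members were Dst, 4618 ± 695 and 5377 ± 192 CPM, and Itga6, 745 ± 195 and 1103 ± 220 CPM, for basal keratinocytes and Krt10, 135 ± 44.8 and 240 ± 175 CPM, for suprabasal ones. With the block 2 of the 16 basal genes rose, Itga6 (0.58, adjusted p = 0.00252) and Itgb4 (0.57, adjusted p = 0.0053), the latter named after its values were seen. Adjusted over the list alone, 2 basal genes rose and 3 fell with the block. T cell, mast cell, adipocyte, skeletal muscle and erythroid markers had 2 to 4 tested members, too few for a test, and summed to 17.7, 11.3, 24.9, 10.8 and 43.1 CPM in control and 19.8, 21.4, 30.9, 11.1 and 67.6 CPM in Bmi1-deleted libraries. The mast cell sum includes Gata2, also on the Polycomb-repressed list, at 2.34 ± 1.41 CPM in control and 11.5 ± 3.87 in Bmi1-deleted libraries. The rise of that sum therefore need not reflect mast cells.

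**Figure D2:**
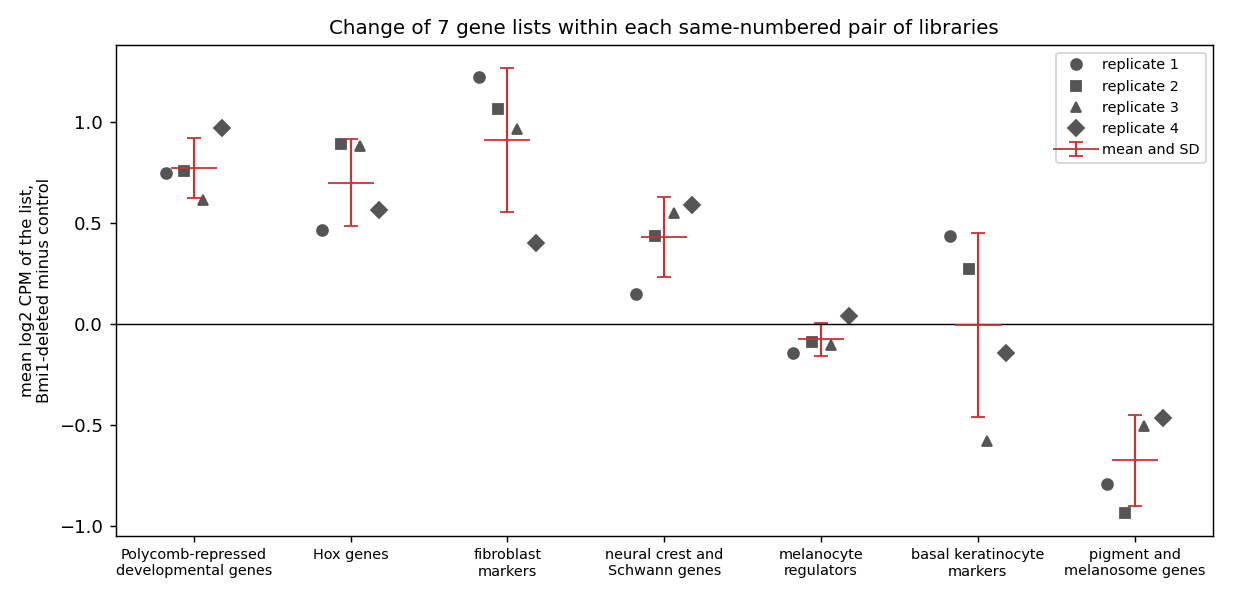
Difference in the mean log2 CPM of 7 gene lists, Bmi1-deleted minus control (vertical axis), in each same-numbered pair of libraries (symbols), with the mean and SD over the 4 pairs. Polycomb-repressed, Hox, fibroblast and Schwann cell genes were above 0 in all 4 pairs, pigment genes below 0 in all 4, and basal keratinocyte markers on both sides.

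No member of the p53, senescence, immediate early, cell cycle, repair or ribosomal lists passed over all genes. Of 35 p53 target genes 0 passed over all genes and 1 rose adjusted over the list alone, and the list was higher by camera (median 0.12, adjusted p = 0.0145; adjusted p = 0.34 with an estimated correlation), a call lost without control 1 (adjusted p = 0.0965) or Bmi1-deleted 1 (adjusted p = 0.0545) and at 10 CPM (0.0902). The p53 target and kinase inhibitor gene Cdkn1a stood at 120 ± 8.37 and 170 ± 18 CPM (adjusted p = 0.144, 0.0268 with the block). With the block it passed in 2 of 4 fits that each left out 1 pair. Secreted factors of senescence (27 tested, median 0.49, adjusted p = 0.0122) and immediate early and heat shock genes (35, 0.20, 0.0155) were higher by camera, and S-phase genes (40, −0.26, 0.00421), DNA repair genes (38, −0.11, 0.0421) and ribosomal protein genes (77, −0.25, 3.15e-09) were lower. None of these 5 held with an estimated correlation (adjusted p = 0.51, 0.561, 0.51, 0.51 and 0.51 with an estimated correlation), and in all 5 lists 0 genes passed over all genes without the block. With the block 1 senescence gene and 2 immediate early genes rose, 2 ribosomal genes fell, and 0 passed in the S-phase and repair lists. Adjusted over the list alone with the block, 6 senescence and 7 immediate early genes rose and 12 ribosomal genes fell. Only the ribosomal list kept its camera call with every library left out in turn. The senescence list lost it without control 3 or 4 or Bmi1-deleted 1 or 2 (highest adjusted p = 0.317), and the immediate early list without the same libraries (0.228). Their medians went down to 0.19 without Bmi1-deleted 1 and 0.03 without Bmi1-deleted 2, and fibroblast markers were higher in the same comparison (median 0.85). The S-phase list lost it without control 4 or Bmi1-deleted 2 (0.252 and 0.0717), and the repair list without control 3 or 4 or Bmi1-deleted 1, 2 or 4 (highest adjusted p = 0.187), with the block (0.0734) and at 10 CPM (0.16). Among abundant members, Timp2, a protease inhibitor, stood at 421 ± 57.5 and 485 ± 58.6 CPM, Fos, an immediate early factor, at 1556 ± 469 and 1873 ± 686, and Pcna, the replication clamp, at 67.8 ± 14.7 and 56.8 ± 7.53. Genes of the G2 and M phases did not pass (39 tested, −0.13, adjusted p = 0.432), with the proliferation marker Mki67 at 67.7 ± 44.6 and 53.9 ± 31.2 CPM, except without control 1 or Bmi1-deleted 3 (adjusted p = 0.0207 and 0.0113).

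Subunits of the Polycomb complexes did not pass. Of 27 genes of complex 1, 0 passed over all genes and 2 rose adjusted over the list alone (median −0.02, camera adjusted p = 0.46). Of 12 genes of complex 2, 0 passed, over all genes or adjusted over the list alone (median −0.16, camera adjusted p = 0.164), and its methyltransferase gene Ezh2 stood at 107 ± 10.1 and 117 ± 12.3 CPM (adjusted p = 0.875). By edgeR 0 genes passed in the lists of oxidative phosphorylation (76 tested, median −0.05, camera adjusted p = 0.143), mitochondrially encoded genes (12, −0.15, 0.149), glycolysis (22, 0.02, 0.819), cholesterol synthesis (23, −0.14, 0.249), the unfolded protein response (28, 0.08, 0.19), apoptosis (25, 0.01, 0.955), interferon response (33, 0.10, 0.192), TGF-beta and BMP signalling (29, −0.06, 0.988), MAPK feedback (19, 0.16, 0.171), lysosome and autophagy (35, −0.10, 0.0815) and histones (25, 0.24, 0.214). WNT targets (27 tested) had a median of 0.02 but a mean below 0 and a test pointing down (adjusted p = 0.213), and 2 fell adjusted over the list alone. With the block 2 of them rose and 3 fell, and 5 rose and 5 fell adjusted over the list alone. With the block 1 MAPK feedback gene and 1 lysosome gene fell, and 1 TGF-beta and BMP gene and 1 gene of complex 1 rose. In the MAPK list 6 rose and 2 fell with the block adjusted over the list alone. In the TGF-beta and BMP list 2 rose and 0 fell, and in the lysosome list 1 rose and 1 fell. Leaving out 1 library brought 7 of the lists named by function here past the threshold. Oxidative phosphorylation passed without control 1 or 3 (adjusted p = 0.0392 and 0.00585), mitochondrially encoded genes without control 1 (0.0207), cholesterol synthesis and interferon response without control 3 (0.00291 and 0.0119), the unfolded protein response and histones without control 4 (0.000554 and 0.0409), and lysosome genes without control 2 or Bmi1-deleted 4 (0.0374 and 0.0405). Histones and lysosome genes also passed with the filter of 10 CPM (adjusted p = 0.0419 and 0.0248).

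Of 38 lists tested, 16 passed by camera with its preset correlation, 0 with an estimated correlation and 2 by fry, the Ink4a/Arf and the Polycomb-repressed lists. The Ink4a/Arf list holds Cdkn2a, whose fitted change lies far above the list's median, so its result need not be list-wide. The exact permutation test of each list's mean level had its smallest two-sided p of 0.0286 for the Hox, Polycomb-repressed and p53 lists (adjusted p = 0.362). As no smaller p is possible with 70 assignments, adjustment over 38 lists left this test almost no room to pass.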

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

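Chosen after the results were seen were the tests of the fibroblast score, of cell type markers against each other, of pigment genes against Dct and of all explanations for the glutathione S-transferase genes; the test of GC content was not. Of 205 groups of 4 libraries examined, 11 held a library far from the other 3 (gap over range above Dixon's critical value), and chance gives about 1 in 20 groups, or 10.2. Cdkn1c in control 1 had 4.68 log2 CPM against 4.22 to 4.28 in the others. Mmp2 in control 2 had 5.15 log2 CPM against 5.55 to 5.63. Sgip1 in control 3 had 5.13 log2 CPM against 5.71 to 5.76. Sox10 in control 2 had 8.47 log2 CPM against 8.75 to 8.80. Onecut2 in Bmi1-deleted 4 had 3.30 log2 CPM against 4.13 to 4.27. Fendrr in control 4 had −0.16 log2 CPM against 1.05 to 1.16. Gstp1 in control 4 had 7.52 log2 CPM against 6.79 to 6.90. The total of Bmi1-deleted 2 was 10368174 counts against 9076517 to 9172699. Gm23935 took 85.6% of TPM in Bmi1-deleted 4 against 82.7% to 82.8%. The S-phase score of control 4 was 3.96 against 3.26 to 3.35. The glycolysis score of control 3 was 5.38 against 5.50 to 5.52.

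Polycomb-repressed developmental regulators and Hox genes were higher in the Bmi1-deleted cells, 0.75 (SE 0.04) on the log2 scale over the 64 tested members of both lists. The lists name 128 and 39 genes, and those left out by the count filter are not covered. The tables argue against fibroblasts carried through the Dct-GFP gate as the whole source: with each library's fibroblast score as a covariate the difference was 0.73 (SE 0.05). They also argue against GC content, whose trend over 15928 genes predicts a median of 0.047 where 0.68 was observed with the block (bootstrap SE 0.17). With the block and the fibroblast score together the difference was 0.93 (SE 0.10), in a fit with 2 residual degrees of freedom. Of the genes followed only Meis2 (5.02, SE 0.85) and Onecut2 (11.22, SE 1.91) passed in it. Onecut2 was not called in the fit of genotype alone, where it had 3.635, so its size here is unreliable. The errors of the other genes grew, from 0.37 to 1.19 for Tbx15 (4.47 before, 5.91 after) and from 0.31 to 0.75 for Foxf1 (2.28 before, 1.97 after). Mural (0.79), endothelial (0.59) and myeloid (0.56) scores were also higher, while basal keratinocyte and hair follicle scores were not. None of these was used as a covariate, so other cell types carried through the gate stay open. A change in the kind of fibroblast carried along stays open, as does the hypothesis that loss of Bmi1 may have released these genes in melanocyte stem cells.

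Pigment genes were lower while fibroblast and Schwann cell genes were higher. A lower share of melanocytes raises the markers of all other cells alike. Fibroblast markers exceeded basal keratinocyte markers by 0.92 (SE 0.22) over the 4 pairs and in 4 of 4, although the basal genes Itga6 and Itgb4 rose with the block. The basal list was chosen for this after its values were seen. Its mean score changed by −0.004, but the pairs went both ways (SD 0.456, 2 of 4 above 0), so it is not a flat reference. Hair follicle markers had −0.028 (SD 0.27, 3 of 4 pairs above 0), and 7 of the 15 tested are also in other lists. The mural (0.79), endothelial (0.59), myeloid (0.56), sebocyte (0.42) and suprabasal keratinocyte (0.40) scores were higher. As a lower melanocyte share would also give such rises, that share is not excluded. Such a share would also lower every pigment gene alike, and 9 pigment genes, picked after the values were seen, changed by −0.19 (SE 0.09) relative to Dct. This was below 0 in all 4 pairs but only just past 2 SE, which over 4 pairs decides nothing. The median of the 25 tested pigment genes was −0.63 (−0.71 with the block), and Dct itself had −0.63 (−0.71 with the block). Kit (0.05, SE 0.06) and Mitf (0.01, SE 0.04) followed Dct, and Sox10 was 0.87 (SE 0.20) above it. Schwann cell markers exceeded basal keratinocyte markers by 0.43 (SE 0.31), which decides nothing, nor does the fibroblast score as a covariate, with which Dct had 0.08 and Mitf 0.00, as with the block added they had −0.19 and −0.28. A lower melanocyte share, a rise of fibroblasts alone in the gate, a rise of Sox10-positive Schwann-like cells alone, and a lower pigment programme within the stem cells all stay open.

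Gsta1 and Gsta2 were named by the rule, which asks for groups that do not overlap, so they were necessarily lower in all 4 pairs. The glutathione S-transferase list that holds them was chosen from memory of the study. Reads moved between paralogs would leave their sum in place, but the summed counts of Gsta1, Gsta2 and Gsta4 changed by −1.72 (SE 0.17), and by −1.61 (SE 0.06) with those of Gsta3, Gm3776 and Gm10639, alpha class genes that were not chosen for this pattern. A lower melanocyte share would lower them no more than Dct. Both genes were chosen for their fall, however, so a comparison with Dct cannot decide this. The sum of Gsta1 and Gsta2 changed by −0.91 (SE 0.17) relative to Dct, and by −1.29 (SE 0.17) with the fibroblast score as a covariate. That score ended the calls that the block gave these genes: with the score and the block Gsta1 had −2.71 (SE 0.72, against −1.42, SE 0.26, with the block alone) and Gsta2 −0.59 (SE 0.69, against −1.89, SE 0.26), as the errors grew and the change in Gsta2 shrank. A lower level within the sorted cells may explain this, as a hypothesis. A lower melanocyte share and a sub-population that expresses both genes and was sorted less often stay open.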

How the results depend on the processing

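Bmi1 stayed below 0 under all alternatives run and passed under none. The 14 higher and 1 lower genes moved with the model, and the cause was not tested unless given. The settings chosen after seeing the data were the 2-level block of replicates 1 and 2 against 3 and 4, the fibroblast score, each pair of replicates alone, the block without 1 pair, TPM without Gm23935 and the block with an estimated correlation. Counts of higher and lower genes were 259 and 121 with no filter, 106 and 52 with DESeq2, 273 and 113 with the replicate block, 267 and 119 with the 2-level block, 150 and 92 with 1 surrogate variable, 37 and 12 at an adjusted p under 0.1, 23 and 5 with the fibroblast score, 83 and 73 in replicates 1 and 2 only, and 7 and 0 with the mitochondrial share. The number of lower genes alone moved with RLE (3), upper quartile (3), 10 CPM (2), voom (4), voom with weights (3), replicates 3 and 4 only (6) and the block with the fibroblast score (10), although in the last 2 only 5 and 1 of the 14 higher genes were still among those called. The number of higher genes alone moved with log2 TPM (1, with 0 of the 14 shared), on which the median of all genes shifted by −0.18, and with TPM without Gm23935 (3), where the shift was −0.01. Of the 380 genes with no filter 275 were also called with the block, as were 126 of 158 with DESeq2 and 222 of 242 with the surrogate variable. Without 1 pair the block gave 264 and 87 (replicate 1), 89 and 24 (replicate 2), 153 and 85 (replicate 3) and 124 and 65 (replicate 4). Leaving out 1 library gave 8 higher and 0 lower (without control 2) to 40 and 5 (without control 1), and 9 higher without Bmi1-deleted 2. Among the genes named and the lists, the replicate block changed no call other than those printed beside their results and those of Krt1 (1.00, adjusted p = 0.0032), Serpine2 (0.71, adjusted p = 0.0141) and Rbl2 (−0.52, adjusted p = 0.0332), which passed with it, and in 3, 2 and 1 of 4 blocked fits without 1 pair.

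Of 35 splits of the 8 libraries into 4 and 4, 2 gave at least the 14 higher genes (highest other 290), 3 at least as many lower (highest other 219) and 5 at least the 16 lists (highest other 17), so chance cannot be excluded for these counts. The split with 290 and 219 genes puts replicates 1 and 2 against 3 and 4, which points to a structure of the samples that the replicate block removes. With the block the real split gave 386 genes and the highest of the other 7 gave 2, but 8 splits are too few for a share under 0.05, and 1 of 8 reached the real count. Without the block the highest other among these 8 was 1 gene against 15.

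Directions reversed only in genes that did not pass without the block. On log2 TPM Sox10 had −0.085 and Ezh2 −0.109, both above the shift of all genes. With the fibroblast score Dct had 0.075, Mitf 0.002, Krt10 −0.708, Pmp22 −0.003 and Serpine2 −0.115, and with the block as well Krt1 had −0.032, Krt10 −1.84 and Rbl2 0.072. Krt10 had −0.283 in replicates 3 and 4 only and Ezh2 −0.005 in replicates 1 and 2 only. Cdkn2b, near the floor, had 0.62 with the mitochondrial share, 0.76 in replicates 1 and 2 only, 0.46 with the block without replicate 4, and −0.62 to 0.36 leave-one-out.

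Lists past the threshold fell from 16 to 0 with an estimated correlation, with or without the block, and to 2 by fry (5 with the block), and ranged from 8 (without Bmi1-deleted 1) to 20 (without Bmi1-deleted 3). List medians near 0 reversed: interferon response −0.003 and WNT targets −0.026 at 10 CPM, and WNT targets −0.081 and complex 1 subunits 0.006 with the block. Leave-one-out medians ran from −0.077 to 0.032 for lineage regulators, −0.07 to 0.09 for complex 1 subunits, −0.37 to 0.26 for G2 and M genes, −0.015 to 0.056 for apoptosis, −0.112 to 0.058 for oxidative phosphorylation, −0.065 to 0.07 for glycolysis, −0.27 to 0.002 for cholesterol synthesis, −0.035 to 0.165 for interferon response, −0.069 to 0.033 for WNT targets, −0.10 to 0.01 for TGF-beta and BMP genes, −0.10 to 0.21 for basal keratinocytes and −0.021 to 0.153 for hair follicle markers.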

Other observations

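The imprinted gene test and its set were fixed before its result was seen, but genes named here were chosen after their values were seen, from the fit with the replicate block. Developmental regulators that missed the threshold without the block passed with it, though not all did so with each pair left out in turn. Onecut2, a homeobox factor of liver and neurons, had a log2 change of 4.01 with the block (adjusted p = 0.00252; passed in 4 of 4 fits without 1 pair), and Gata2, a blood and mast cell factor, 2.41 (adjusted p = 0.0053; 3 of 4, highest 0.0549). The RNA-binding protein Igf2bp1, a paralog of Igf2bp3, had 3.33 (adjusted p = 0.00587; 2 of 4, highest 0.0864), and Fendrr, the non-coding neighbour of Foxf1, 2.41 (adjusted p = 0.0212; 1 of 4, highest 0.142). Lhx2, a homeobox factor of hair follicle stem cells, went the other way, −1.23 (adjusted p = 0.0147), and was not refitted without pairs. The late melanocyte genes Trpm1, an ion channel (−1.08, adjusted p = 0.00291), and Mlana, a melanosome protein (−1.06, adjusted p = 0.00595), fell with the block, and passed in 4 and 3 of the 4 fits (highest for Mlana 0.0811). Tgfbr3, a co-receptor of TGF-beta, had 0.62 (adjusted p = 0.00167) and passed in all 4.

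As 3 of the 14 genes that rose are imprinted (Cdkn1c, Peg3 and Zdbf2), a hypothesis was that imprinted genes as a set may be higher after loss of Bmi1. Among 29 tested imprinted genes not seen among the leading genes the median log2 change with the block was 0.19 and 3 rose (0 without the block), a result consistent with it. For these 29 the p from camera of limma was 0.00482, and 0.183 with an estimated correlation. Of all 34 tested, with the seen ones, 7 rose with the block and 1 fell, Plagl1 (−0.72, adjusted p = 0.000756), which is named after its values were seen. Several imprinted genes are high in fibroblasts, whose markers were also higher, so the hypothesis stays open.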
